A study of Mus musculus with 12 samples.

How the data were processed

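Lung RNA had been hybridised to Affymetrix arrays, 10 arrays of one version and 2 of another. Per the series' design text, large airways and the structures between the lungs were taken off at dissection. The authors deposited one intensity per probe set and array on a linear scale. The software, background correction and summary method behind the deposited intensity values are not given in the sources used here. The trimmed mean without 2% of values at each end was between 1500.1 and 1500.8 on every array, so the deposited intensities were treated as scaled already and were used as they stood.

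The main table holds 12488 probe sets and the other 12654. The arrays' 66 control probe sets were left out of tests, a step not written in the design fixed before the data were examined, leaving 12422. Of these, 10833 have 1 gene symbol in the platform annotation, 396 several and 1193 none, and no gene was named from a probe set with several. Gene identifiers were checked against the RefSeq table of assembly GRCm38.p6, used only for names and for which genes neighbour each other. No coordinates are given, since the build behind the files is not given in the sources used here.

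Intensities under the 20th percentile of the table (109 in the main table and 85.7 in the other) were set to that value and log2 was taken. Probe sets whose mean was under the 40th percentile (4969) were left out, and 7453 were tested. Knockout and wild-type arrays were compared with limma 3.58.1 (lmFit and eBayes) in R 4.3.3, with the littermate pair as a block, two-sided, and Benjamini-Hochberg adjustment over all probe sets tested at a threshold of 0.05. Standard errors come from that fit. The tables of the 2 array versions were scaled separately, so the pair on the other version entered no test.

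The pairing rests on the series text, which speaks of littermates matched for sex, and on numbers shared by the sample titles. As a check, deviations from the group means of same-numbered arrays correlated across probe sets at 0.421, 0.375, 0.27, 0.346 and 0.531 in pairs 2, 2b, 3A, 3B and 4A, all over 0.1. The highest correlation of each knockout array with a wild-type array of another number was 0.331, 0.45, 0.317, 0.282 and -0.142 in that order, so in pairs 2b and 3A it exceeded that of the same number, and this check alone does not single out the littermate there. Xist and Y-linked transcripts gave both members of all 6 pairs the same pattern. It was male in pair 4A (Xist 16.2 and 16.5, Y-linked mean 381 and 566 in knockout and wild type) and female in the others. Where samples of the same group were compared no 2 arrays were duplicates. The knockout arrays of pairs 2 and 2b lie in different groups by transgene and were the most alike of all (log2 intensities correlated at 0.985). Arrays of pairs 2 and 2b correlated with each other at 0.972 or more, and all other arrays at 0.971 or less. The main test counts them as separate pairs. The labels do not say outright that each array is a separate animal, so p-values of the probe set test measure only the spread between these samples. Ages were not assigned to arrays, but the pair block takes up age where littermates share it.

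The 49 gene lists were fixed before the data were examined and covered pathways, cell types and markers of neighbouring tissue or handling. The last kind took in the immediate early, glucocorticoid-responsive, ribosomal protein, heart muscle, and skeletal muscle and oesophagus wall lists. The probe set with the highest mean represented each gene, and 46 lists had at least 3 measured members. They were tested with limma's camera, with a preset inter-gene correlation of 0.01 and adjustment over the lists. With that preset its p-value sets a list against the spread between genes and does not measure the spread between pairs. The same test with an estimated correlation, fry, and an exact sign-flip test of the 5 pair means were run beside it. The remaining 3 lists held 1 measured gene each (Aqp1, Chia1 and Xist) and were not tested. A mean log2 ratio of a list is over its members and its SD over the 5 pairs.

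Genes were named by a rule also fixed in advance: 15 rising and 15 falling past the threshold with the same direction in every pair, or, if fewer than 10 passed, the 12 rising and 12 falling of smallest p with the same direction in every pair. No probe set with 1 symbol passed, so the second part applied. Cftr was always named, in each list up to 3 members of smallest p, and for the interaction the 8 of smallest p. Other genes named beside the list of muscle and oesophagus genes were chosen after their values were seen.

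Alternatives were quantile normalization, scaling to a common median, floors at the 10th and 30th percentile, no filter or a filter at the 60th, array weights, a variance trend with robust estimation, leaving out each pair, no pair block, the pair as a random effect, the transgene as a covariate, other thresholds and an unmoderated paired test. For lists, another correlation, fry and the mean of all probe sets of a gene were tried. Averaging pairs 2 and 2b, and the squamous genes as a covariate, were added after seeing the data. The steps were tested on simulated arrays with the real spread and 200 probe sets changed. For the main comparison 82.1% of changes of log2 1, 92.5% of log2 2 and 98.5% of log2 3 were called, with 4 false calls among 7453 probe sets; for the 3 pairs with the transgene it was 35.8%, 86.6% and 89.4%. These shares hold with 200 probe sets changed. With fewer changed, the adjustment asks for a smaller p, so they do not give the share found in these data. Cftr itself, with a log2 ratio of -0.92, had a limma adjusted p of 0.265. Of 46 lists, 5 of 5 shifted by a log2 of 0.5 were called, and none of the others. The simulated noise was independent between probe sets, whereas the estimated inter-gene correlation was 0.35 in the skeletal muscle and oesophagus wall list. The simulation therefore does not measure how often lists are called falsely in these data.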

Results

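Lung RNA of mice lacking Cftr, the gene of the chloride channel that is defective in cystic fibrosis, was compared with that of wild-type littermates of the same sex. There were 12 Affymetrix arrays, 6 from knockout and 6 from wild-type animals, in 6 numbered littermate pairs. All mice had a mixed FVB/N and C57BL/6 background, and the ages of 3, 6 and 11 weeks given for the series are not assigned to single samples. By label, 4 knockout and 3 wild-type arrays came from mice with the transgene FABP-hCFTR, a human CFTR under a fatty acid-binding protein promoter that is used to supply the channel to the intestine, and 2 knockout and 3 wild-type arrays from mice without it. Pairs 2, 2b, 3A, 3B and 4A were measured on one array version, and pair 1A on another. The median intensity per array lay between 516 and 674. In pair 4A the ratio of 3' to 5' probe signal was 1.49 and 1.84 for Gapdh and 3.25 and 3.17 for actin (knockout and wild type), whereas on the other 8 arrays of that version it did not exceed 0.908 and 1.76. The number of arrays limits the precision of every comparison.

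The targeted gene was examined first. Cftr intensity was 743 ± 180 in knockout and 1375 ± 145 in wild-type lungs (SD, n = 5 each). It was lower in the knockout array of 5 of 5 pairs, with a log2 ratio of -0.92 ± 0.13 (SE). In pair 1A the values were 1025 and 2147. The limma test gave an adjusted p of 0.265 over all probe sets tested, and 0.00294 adjusted over the list alone for the 18 measured anion channel and transporter genes. The other Cftr probe sets had mean intensities from 12.4 to 71.2, under the floor of 109, and were not tested. Where the probes lie relative to the disrupted part of the gene was not analysed here, so residual signal does not check the labels.

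**Figure D1:**
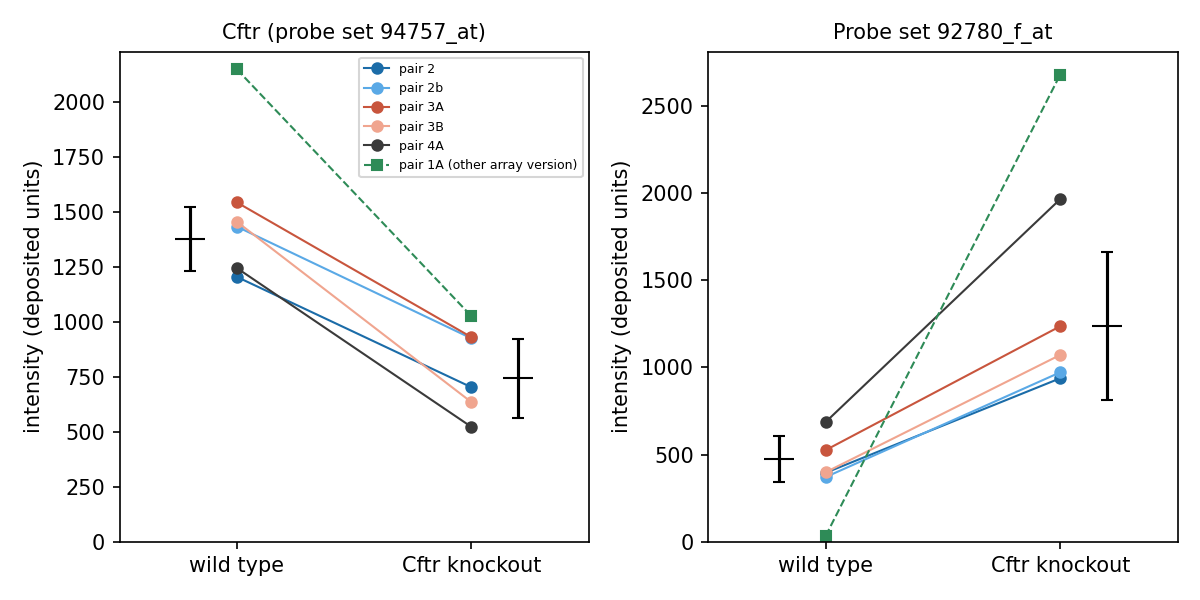
Intensity (deposited units, linear axis from 0) of Cftr and of the probe set without a gene symbol in wild-type and knockout arrays, with a line joining each littermate pair; black bars give mean ± SD of the 5 pairs on the main array version, and the green dashed line is pair 1A on the other version. Cftr was lower in every knockout array than in its littermate (743 against 1375 on average), and the unnamed probe set was higher (1237 against 476).

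The main question was which transcripts differ between Cftr knockout and wild-type lungs. A single probe set, which has no gene symbol in the annotation used and is called the unnamed probe set here, rose in knockout lungs, from 476 ± 133 to 1237 ± 423 (SD, n = 5 each), a 2.57-fold difference. Among transcripts named by the rule fixed in advance, none of which passed the threshold, Errfi1, a feedback inhibitor of EGF receptor signalling, had a log2 ratio of 0.69 ± 0.082 (SE), and 0.98 on its other probe set. Fos, an immediate early transcription factor, had 0.68 ± 0.11. The neutrophil calcium-binding proteins S100a8 and S100a9 had 0.86 ± 0.16 and 0.85 ± 0.17, and the erythroid transcription factor Klf1 had 1.24 ± 0.23. The other transcripts among the 12 of smallest p higher in all 5 pairs were Chia1 (log2 ratio 0.52), Wfdc21 (0.57), Bmpr1a (0.52), Ss18l2 (0.43), Pacsin1 (1.03), Ly6d (0.88) and Mrps10 (0.52).

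On the lower side, besides Cftr, the proteasome activator Psme3 had a log2 ratio of -0.70 ± 0.097 (SE), the collagen VI chain Col6a2 -0.50 ± 0.088 and the phospholipid transfer protein Pltp -0.44 ± 0.089. Sox18, an endothelial transcription factor, had -0.43 ± 0.089, and -0.35 on its other probe set. Rpl19 had -1.46 ± 0.30 on one probe set and 0.17 on its other, so its probe sets disagree. The remaining transcripts among the 12 of smallest p lower in all 5 pairs were Zc3h3 (log2 ratio -0.50), Nfatc2 (-0.58), Pccb (-0.47), Zmat3 (-0.53), Ranbp10 (-0.67) and Pmm2 (-0.52). For these 24 transcripts the adjusted p lay between 0.261 and 0.537.

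Of 7453 probe sets tested with limma within pairs, 1 passed an adjusted p of 0.05, the unnamed one (log2 ratio 1.36 ± 0.090, SE; adjusted p = 0.0102; higher in 5 of 5 pairs). At an unadjusted p under 0.05 there were 619 probe sets where chance gives 373, and at an unadjusted p under 0.01 there were 127 where chance gives 74.5, of which 70 were higher and 57 lower. The 127 became 76 without pair 2, 70 without pair 2b, 64 with both averaged and 55 without the pair term. In 788 probe sets (10.6%) the knockout array lay on the same side in all 5 pairs. Chance gives 6.25% only if the pairs are independent, and the differences of pairs 2 and 2b correlated at 0.443; the pattern with pairs 3A and 3B on the side opposite to the other pairs held 9.18%. The call of the unnamed probe set ended when the pair term was left out (adjusted p = 0.892) and when any 1 pair was left out (adjusted p from 0.0614 to 0.143), while its log2 ratio stayed between 1.32 and 1.39 without each pair. It also ended with pairs 2 and 2b averaged (adjusted p = 0.0992), with the squamous genes of each array as a covariate (adjusted p = 0.718), both chosen after seeing the data, and with the transgene as a covariate in place of the pair (adjusted p = 0.902), and a filter at the 60th percentile left the probe set untested.

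Gene lists fixed in advance were tested for a joint shift. Neutrophil genes rose by a mean log2 of 0.31 ± 0.17 (SD, n = 5 pairs; camera adjusted p = 0.00356; adjusted p = 0.442 with an estimated correlation), with 10 of 12 members higher. S100a8, S100a9 and Elane passed when adjusted over the list alone, and Elane, a granule protease, was lower with a log2 ratio of -0.43. Cholesterol synthesis genes rose by 0.16 ± 0.053 (camera adjusted p = 0.0015; adjusted p = 0.442 with an estimated correlation), with 12 of 14 higher; Idi1 (0.40) and Fdps (0.41) passed when adjusted over the list alone. With the squamous genes of each array as a covariate the cholesterol synthesis list had 0.12 and no longer passed (adjusted p = 0.196). Immediate early genes, a list fixed as a marker of handling or neighbouring tissue, rose by 0.19 ± 0.14 (camera adjusted p = 5.08e-05, or 0.442 with an estimated correlation). Of them 21 of 27 were higher, and Fos and Ccn2 (0.61) passed when adjusted over the list alone.

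Genes of oxidative phosphorylation rose by a mean log2 of 0.12 ± 0.052 (SD, n = 5 pairs), with 35 of 41 members higher, among them Uqcrc2 (0.30) and Cox7b (0.24), although the ATP synthase subunit Atp5g1 had -0.37. Proteasome subunits rose by 0.12 ± 0.087, with 23 of 27 higher, and ribosomal proteins by 0.11 ± 0.11, with 20 of 22 higher. The camera adjusted p was 0.000336, 0.000371 and 0.00272 for these lists in turn, and the adjusted p was 0.442, 0.489 and 0.509 with an estimated correlation. With the squamous genes of each array as a covariate oxidative phosphorylation had 0.071 (adjusted p = 0.463) and the proteasome 0.042 (adjusted p = 0.671), and neither passed. Without pair 3B the ribosomal list had 0.060 and no longer passed (adjusted p = 0.159). Collagens, elastin and matrix genes fell by a mean log2 of 0.12 ± 0.13 (SD, n = 5 pairs; camera adjusted p = 0.00182; adjusted p = 0.489 with an estimated correlation), with 15 of 50 higher. Col6a2 passed when adjusted over the list alone, and Col15a1 (-0.54) and Col6a3 (-0.31) did not. The matrix list no longer passed without the pair term (mean log2 -0.12, adjusted p = 0.0715) or with the squamous covariate (mean log2 -0.11, adjusted p = 0.0698).

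Lists of muscle, oesophagus and stress response genes were tested in the same way. The skeletal muscle and oesophagus wall list rose by a mean log2 of 0.77 ± 0.85 (SD, n = 5 pairs; camera adjusted p = 3.95e-05; adjusted p = 0.489 with an estimated correlation), from -0.082 in pair 3B to 2.04 in pair 4A. The squamous keratin Krt13 had log2 ratios of 5.20, 5.28 and 6.07 in pairs 2, 2b and 4A and of at least 1.66 in pair 3A, where the wild-type array was at the floor, and has no ratio in pair 3B, where both arrays were. Krt4 had 3.66, 2.98, -0.37, -0.25 and 5.57 in pairs 2, 2b, 3A, 3B and 4A. No member passed over all probe sets or over the list alone. Heart muscle genes rose by 0.17 ± 0.25 (camera adjusted p = 0.0211; adjusted p = 0.509 with an estimated correlation), and Mybpc3 (-0.49) ran against the list. This list no longer passed without pair 2 (adjusted p = 0.289) or without pair 2b (adjusted p = 0.234), and with the squamous covariate it had 0.023 (adjusted p = 0.992). Glucocorticoid-responsive genes rose by 0.19 ± 0.40 (camera adjusted p = 0.0012, or 0.489 with an estimated correlation). They were higher in pairs 2 (0.62), 2b (0.56) and 4A (0.18) and lower in pairs 3A (-0.17) and 3B (-0.23). Errfi1, Klf9 (0.53) and Per1 (0.73) passed when adjusted over the list alone.

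**Figure D2:**
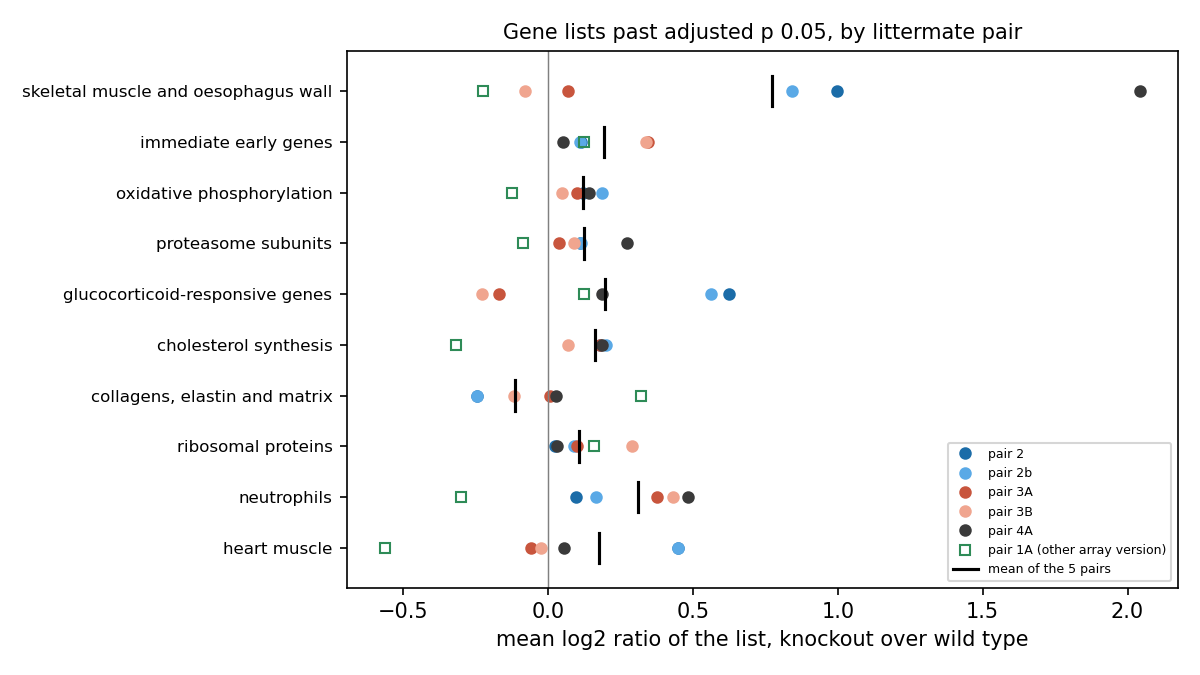
Mean log2 ratio (knockout over wild type) of the 10 gene lists past the camera threshold; filled circles are littermate pairs on the main array version, black bars their mean, and open squares pair 1A on the other version. Means of pair 1A are over all list members on that version, without the intensity filter. Between the 5 pairs on the main version the skeletal muscle and oesophagus wall list spans -0.082 to 2.04, and cholesterol synthesis 0.068 to 0.20.

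**Figure D3:**
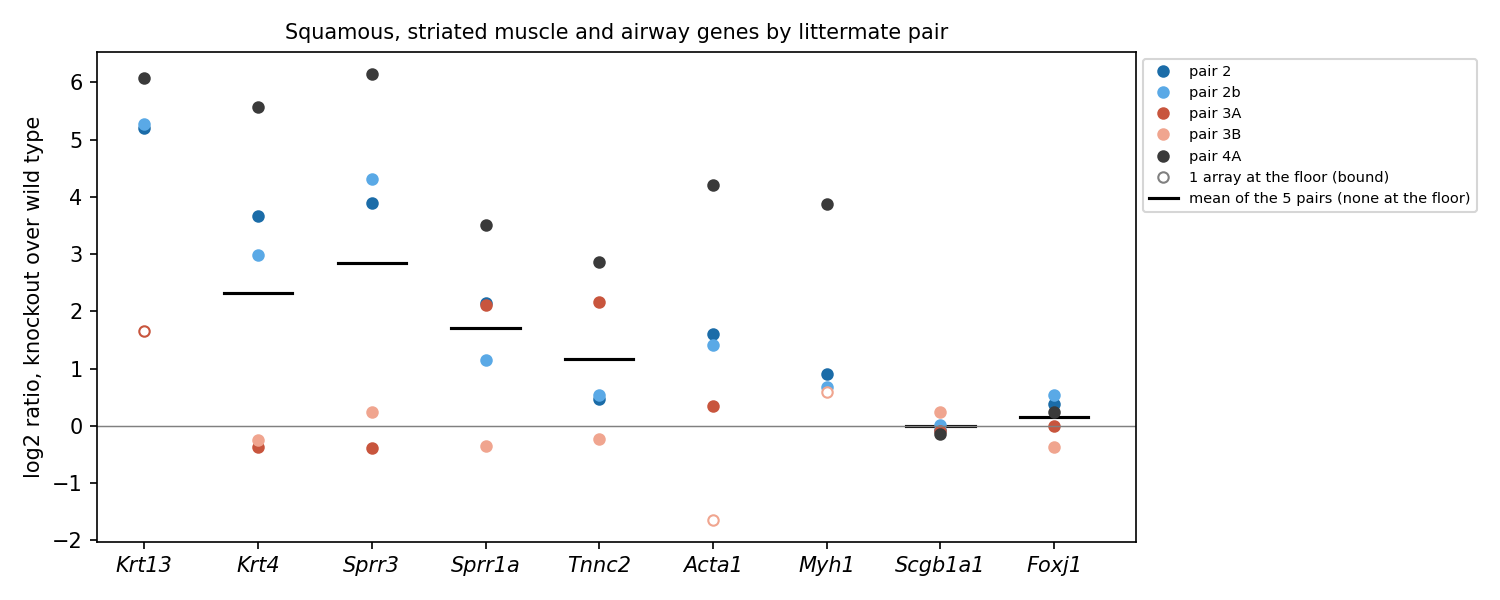
Log2 ratio (knockout over wild type) in each of the 5 littermate pairs for squamous genes (Krt13, Krt4, Sprr3, Sprr1a), striated muscle genes (Tnnc2, Acta1, Myh1) and airway genes (Scgb1a1, Foxj1), with black bars for the mean of genes with no array at the floor; open circles are bounds, since 1 array was at the floor, and pairs with both arrays at the floor are not drawn. The mean was 2.32 for Krt4, 1.16 for Tnnc2 and -0.0095 for Scgb1a1.

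In all, 10 of 46 lists with at least 3 measured members passed with the preset correlation, 9 up and 1 down, and 0 passed with an estimated correlation. The exact sign-flip p over 5 pairs cannot go under 0.0625, and 6 of the 10 lists were at that value. It was 0.1875 for the muscle and oesophagus list, 0.25 for the matrix list and 0.375 for the glucocorticoid-responsive and heart muscle lists. Entering the mean of the squamous genes of each array as a covariate, chosen after seeing the data, gave 4 lists past the threshold, among them the immediate early, ribosomal protein and neutrophil lists. The immediate early and ribosomal protein lists had been fixed as markers of neighbouring tissue or handling. The covariate ended the calls of the other 7 of the 10 lists. A lost call alone does not show that a shift followed the squamous genes, since the covariate also costs precision. With it the matrix list stayed at -0.11, the unnamed probe set at 1.31 and Cftr at -0.91. The skeletal muscle and oesophagus wall list turned to -0.19 (adjusted p = 0.196) and the glucocorticoid-responsive list to -0.14 (adjusted p = 0.992). The 6 squamous genes in the covariate are among the 25 members of the muscle and oesophagus list, so that list's turn was in part fixed in advance. Lists of club cells, ciliated cells, alveolar type I and type II cells, endothelial cells and macrophages did not pass. Over single lists alone, Tff2 (log2 ratio 0.80, mucins and goblet cells), Sox18 (endothelial cells), Hspb8 (0.56, cytosolic heat shock proteins), Ly6d (B and plasma cells, and thymus), Klf1 (red blood cells) and Per1 (circadian clock genes) also passed. The lists themselves did not pass, and those of red blood cells, B and plasma cells and thymus had means of 0.0084, 0.030 and 0.0097. Ly6d had 1.01, 1.02, 0.61, 0.21 and 1.55 in pairs 2, 2b, 3A, 3B and 4A.

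In the 3 pairs in which both animals carried FABP-hCFTR, S100a8 and S100a9 had mean log2 ratios of 1.13 ± 0.16 and 1.18 ± 0.041 (SD, n = 3 pairs), Pacsin1 1.27 ± 0.65, the unnamed probe set 1.39 ± 0.14 and Cftr -1.06 ± 0.29. None passed: the limma test called 0 probe sets at an adjusted p of 0.05, with 414 at an unadjusted p under 0.05 and a smallest adjusted p of 0.796. Among pairs without the transgene, pair 2b stood alone on the main array version and has no replicate there. Its log2 ratios were 0.38 for S100a8, 0.37 for S100a9, 1.39 for the unnamed probe set and -0.63 for Cftr. In pair 1A the values were -0.76 for S100a8, -1.26 for S100a9 and -1.07 for Cftr.

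Whether the knockout effect depended on the transgene was tested as an interaction over 3 pairs with it and 1 without. Clca1, a secreted goblet cell protein, had a log2 ratio of at least 4.29 in pair 2b, where the wild-type array was at the floor, and of -0.81, -0.15 and -0.75 in pairs 3A, 3B and 4A. The immunoglobulin heavy chain Ighm had 3.42 in pair 2b and 0.052, -0.14 and 0.18 in those pairs, and the MHC class I gene H2-K1 had 1.25 and -1.89, -1.69 and -1.17. These values are from 1 probe set each: in pair 2b the other Ighm probe sets had 0.62, -0.34 and -1.27, and the other H2-K1 probe sets -0.39 and 0.043. In pair 2, whose knockout carried the transgene and whose wild type did not and which was left out of this test, the log2 ratios were 2.91 for Clca1, 3.25 for Ighm and 1.15 for H2-K1, on the same side as in pair 2b. In pair 1A, without the transgene, Clca1 had -0.22 on another probe set. Mfap4, Entpd5, Nr1d2, Mau2 and Lpl followed by p, with interaction terms of 2.37, -2.45, -1.89, 1.87 and -1.70. No probe set passed: limma called 0, with 265 at an unadjusted p under 0.05 and a smallest adjusted p of 0.319, while the variant with a variance trend and robust estimation called 1. In simulated data of the same layout the interaction test called 0 of 66 probe sets changed by a log2 of 3, so this test could not detect such differences; the variant was not simulated.

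Pair 1A on the other array version was compared by direction alone. Cftr was lower in its knockout array (log2 -1.07), and the unnamed probe set was 2680 in the knockout and 34.6, under that table's floor of 85.7, in the wild type, a log2 difference of at least 4.97. Errfi1 (0.48) and Klf1 (0.34) had the same direction as in the other pairs, and S100a8 and S100a9 the opposite one. Of the 127 probe sets at an unadjusted p under 0.01, 106 were present by identifier and 48 of these (45.3%, exact 95% interval 35.6 to 55.2) had the same sign. Their median signed log2 ratio was -0.053, at percentile 8.74 of 10000 random lists matched on mean expression. Of the 10 lists past the threshold, those of oxidative phosphorylation (-0.13), cholesterol synthesis (-0.32), neutrophils (-0.30), heart muscle (-0.56), skeletal muscle and oesophagus wall (-0.23) and the proteasome (-0.089) were lower in this pair, and matrix genes higher (0.32), against the direction in the other pairs. Immediate early (0.12), glucocorticoid-responsive (0.12) and ribosomal protein genes (0.16) had the same direction. These means are over all members on that version without the intensity filter, so the genes differ. They were 36 against 25 for muscle and oesophagus, and 20 against 12 for neutrophils. Of the squamous genes named for that list, Sprr1a (1.63) and Sprr3 (1.93) were higher in the knockout of pair 1A, and Krt13 had -0.21.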

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

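The tests on oesophagus and on airway share were chosen only after the result was seen, and those on the neighbours of Cftr and on H2-K1 and Ighm after the pattern was seen but before the values they measure; the splits of the arrays were not.

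Squamous and striated muscle genes were higher in knockout arrays of pairs 2, 2b and 4A, with squamous means of 2.66, 2.51 and 3.88 on the log2 scale, against 0.60 and -0.11 in pairs 3A and 3B, where Krt13 was at the floor in 1 and 2 arrays. A larger share of the conducting airway already present in wild-type lungs, taken as a whole, is argued against. Club and ciliated cell genes had a mean log2 ratio of 0.11 with an SE of 0.079, where the squamous genes had 1.91. By pair they had 0.27, 0.086, -0.115, 0.018 and 0.31 in pairs 2, 2b, 3A, 3B and 4A, so they too were highest in pairs 2 and 4A. Airway with few club and ciliated cells is not covered by this test. In pair 1A, on the other array version, Sprr1a and Sprr3 had log2 ratios of 1.63 and 1.93, and Krt13 had -0.21. Oesophagus carried over with the lung stays open and may contribute. The 19 measured muscle members, squamous genes left out, had a median log2 ratio of 0.34, at percentile 100 of 10000 random lists matched on mean expression, but this restates the pattern and its outcome was known, so it does not bear the explanation out. Dissection was meant to remove structures between the lungs, and a squamous change of the knockout epithelium itself was not tested.

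More probe sets lay at an unadjusted p under 0.05 than chance gives (619 against 373). Strain alleles carried with the targeted chromosome might add to this: of 33 tested probe sets of the 50 protein-coding genes on each side of Cftr, 4 (12.1%) lay under 0.05, against 8.12% of the others, at percentile 73.9 of random lists. With 33 probe sets this neither excludes the explanation nor bears it out, and the position of the unnamed probe set was not analysed here. Among the splits of the 10 arrays into 5 and 5, 8 of 100 called at least 1 probe set, the highest other being 79. At an unadjusted p under 0.01, 10 of 100 gave at least 127, the highest other being 462. Both shares lie over the 0.05 below which, by a rule fixed beforehand, chance was to be excluded. The splits with 79 and 462 part pair 4A alone and repeat 1 fit, so they do not measure chance for a contrast of 5 pairs. Not all large counts came from that fit. A split that parts 3 pairs made 19 calls, with 222 at an unadjusted p under 0.01. Another that parts 3 pairs had 129 at that p and no call. The 100 hold all 16 splits that part every pair, and there the highest other counts were 0 and 128. Of those 16, the real split alone made a call, and 2 gave at least 127, the real one included. With 16 splits a share under 0.05 cannot be reached, so chance could not be excluded for either count. Pair 4A differed from the other pairs of the main array version in sex pattern and in 3' to 5' ratios. Its differences also had the largest SD over probe sets (0.627, against 0.411 to 0.433).

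H2-K1 and Ighm had knockout effects of opposite sign or very different size between pairs. A sequence difference between alleles of the mixed background under the probes of 1 probe set is a candidate explanation. The 5 other tested probe sets of these genes had a median range of 0.85 on the log2 scale between pairs, against 3.35 for the 2 leading ones, a ratio of 0.253. The leading ones were picked for a large difference, and 2 of the Ighm probe sets also ranged over 2.30 and 2.07. The transgene's interaction test did not pass (limma adjusted p = 0.319 for Ighm and 0.997 for H2-K1) and had little power. In pair 2, where by label only the knockout carried the transgene, the leading probe sets had 3.25 (Ighm) and 1.15 (H2-K1). In pair 2b, without it, they had 3.42 and 1.25, so these 2 pairs did not part by the knockout's transgene. That is 1 pair of each kind, so the transgene stays open, and the family of each pair was not tested.

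For the gene lists, 22 of 100 splits gave at least 10 lists past the threshold, the highest other being 23. Of the 16 that part every pair 4 did, the highest other being 12. Both shares lie over the 0.05 fixed beforehand as the limit. A count of 10 lists was thus not unusual among the splits, and chance is not excluded. In the 3 pairs with the transgene the real count was 0 calls. Every one of the 10 splits therefore gave at least as many by construction, and the comparison decides nothing. The highest other count was 15, in splits that part 1 pair, and 0 among those that part all 3. In any case 10 splits are too few for a share under 0.05.

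In 60 sets of 5 pair differences, 3 had a value far from the other 4, as many as chance gives. Lss had 0.40 in pair 3A, the cholesterol synthesis list 0.068 in pair 3B and the ribosomal protein list 0.29 in pair 3B. Nr1d2, a clock gene, had 1.68 in pair 2b and 0.059 in pair 1A, both without the transgene, and was below 0 in all 3 pairs in which both animals carried it, but had 1.47 in pair 2, whose knockout carried it; the interaction in the main table had an adjusted p of 0.997, and the difference including pair 1A was not tested.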

How the results depend on the processing

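Averaging pairs 2 and 2b and the squamous covariate were chosen after seeing the data; the other alternatives were fixed before the data were examined, and the cause of each change was not tested unless stated. Cftr kept its sign and stayed short of the threshold in all 19 alternatives (log2 -0.99 to -0.83; adjusted p 0.0688 to 0.902). Pair 2 is the pair of unequal transgene labels, so leaving out either is the same fit, and counts of alternatives include it under both names. The filter at the 60th percentile removed the unnamed probe set and called 0. Of the 18 alternatives that tested the unnamed probe set, 8 called it. Its log2 ratio was 1.36 without the replicate block, 1.28 without the block and with the transgene as a covariate, 1.39 without the pair of unequal transgene labels, 1.37 with pairs 2 and 2b averaged, 1.31 with squamous genes as a covariate, and 1.32 to 1.39 without each pair, each time at an adjusted p over 0.05 (0.0614 to 0.902) and with 0 probe sets called at that threshold; without pair 4A (0.0614), without pair 3A (0.0849) and with pairs averaged (0.0992) it was under 0.10. The unmoderated paired test called 0, no filter 2, a variance trend 3 and an unadjusted p under 0.01 127. At an unadjusted p under 0.01 there were 254 without the filter, 55 without the replicate block, 57 with the transgene covariate as well, 76 without the pair of unequal labels, 64 with pairs averaged, and 70 to 140 without each pair, where fewer arrays entered. Lists past the threshold numbered 19 with array weights, 16 with a variance trend, 0 with an estimated correlation, 0 with directional fry, 4 with the squamous covariate and 9 to 16 without each pair. The interaction had 1 call with a variance trend and 0 in the other alternatives; the transgene pairs had 0 in all of theirs. No paired analysis was possible because only pair 2b lacks the transgene in the main table, so none was run for pairs without it. With the squamous covariate the muscle and oesophagus list turned to -0.19, the glucocorticoid-responsive list to -0.14, Nedd4 to -0.10, Echs1 to -0.048, Aldh3a1 to -0.34, Dlk1 to 0.11, Bpifb1 to -0.20, Foxj1 to -0.17, Gzmb to 0.039, Kit to 0.044, Hdc to -0.037, Slc4a1 to 0.25, Sprr3 to -0.34, Csrp3 to -0.16 and Chad to -0.25. The squamous covariate is made of members of the muscle and oesophagus list, so the turn of that list was in part fixed in advance. With the transgene covariate Dnajb1 turned to 0.0060 and Chil1 to -0.012. Without each pair Chad ranged from -0.061 (pair 4A) to 0.086, being -0.025 without pair 2, the pair of unequal labels, and Col9a3 from -0.071 (pair 2b) to 0.12. Errfi1 passed without the filter and with a variance trend, and in no other alternative. Heart muscle genes passed in 12 of 19 alternatives.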

Other observations

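Lists that did not pass held further differences between pairs. T and natural killer cell genes had a mean log2 ratio of -0.28 ± 0.47 (SD, n = 5 pairs; camera adjusted p = 0.0594), with -0.70, -0.56 and -0.58 in pairs 2, 2b and 4A and 0.11 and 0.35 in pairs 3A and 3B. Mucin and goblet cell genes had 0.35 ± 0.39 (camera adjusted p = 0.0929), with 0.75 and 0.79 in pairs 2 and 2b and 0.076, 0.15 and -0.018 in pairs 3A, 3B and 4A. Of its 6 members Clca1 had 2.91 in pair 2 and at least 4.29 in pair 2b. Without Clca1, a check chosen after its values were seen, the list had 0.20 ± 0.095, with 0.32 and 0.086 in pairs 2 and 2b; the trefoil factor Tff2 had 0.80. Across probe sets, which are not independent replicates, the differences of pairs 2 and 2b correlated at 0.443, and those of pair 4A with pairs 2 and 2b at 0.254 and 0.23. The remaining correlations, that of pairs 3A and 3B (0.0639) among them, lay between -0.0486 and 0.0787.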
